A study of Saccharomyces cerevisiae with 177 samples.

How the data were processed

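Per the labels, the series held 177 libraries of newly made RNA from Saccharomyces cerevisiae, in 60 groups of 1 strain and 1 treatment, with replicates A, B and C. Per the labels' protocols, cells grew at 30 °C in synthetic complete medium to mid-log phase, were labelled for 5 min with 4-thioU and gave libraries made with the Ovation Universal RNA-seq System kit. Most strains carried a Mediator subunit or another factor fused to an IAA7 degron. These were treated with 3-indoleacetic acid (3IAA), which triggers breakdown of the tagged protein, or with DMSO. Other strains carried deletions or mutations, and 1 experiment crossed Med15 depletion with the stresses labelled HS and SM. The labels do not say that replicates came from separate cultures, so each p-value measures the spread between these samples.

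Per the submitters' processing notes, Bowtie2 and HTSeq were used, and the genome builds were sacCer3 and ASM294v2. Versions, the role of the second build and the basis of any scaling are not given in the sources used. Reads were not used, only the deposited value of each gene. Per the file headers, the 15 libraries of the stress experiment held counts, and the other 162 held a deposited value that the authors' files call signal, written with 2 decimals. Each file had the same 5794 genes, of which 5792 were matched by systematic name to the reference annotation. No libraries were identical (0 pairs), and no value column was unused (0 columns).

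In 102 of the 162 signal libraries, low values lay close to multiples of 1 step, so that whole reads could be recovered: within 0.1 of a step, at least 95.61% of the low values were whole. Their recovered totals ran from 2119024 to 10711585 reads. The other 60 libraries had no such step, and their depth is not known. The stress libraries had 4384651 to 10032201 counts.

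Signal was analysed on the deposited scale, without further scaling. Genes with a mean signal of at least 10 over the libraries compared were tested with limma on log2 of signal plus 1, with a mean-variance trend in the empirical Bayes step. This was the fallback that the design gave for values already scaled by the authors, unless whole reads could be recovered. Limma was kept even where they were, with edgeR on recovered reads as another setting. On the deposited scale, a shift shared by every gene counted as a change. Counts of the stress experiment were tested with edgeR, with a quasi-likelihood F test and TMM scaling over all 15 libraries, after edgeR's own filter on low counts. These comparisons cannot show a shift shared by all genes. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene changed when its adjusted p was under 0.05. Log2 changes are given with their standard error (SE), and levels as mean ± standard deviation (SD) in units of signal or, for the stress experiment, TMM-scaled CPM. The count behind each mean was 3 libraries, except for Med7_EWE3 (2 libraries) and for Med21_EWE4 and its control (2 libraries each).

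There were 22 degron comparisons of 3IAA with DMSO, 6 comparisons of mutants with a control strain, 4 stress comparisons and 12 differences between the changes of a pair of comparisons. Controls of the mutants were chosen from the genotype labels: WT for med15del and med16del, Med7_WT for med7N_del and Med7_EWE3, Med21_WT for Med21_EWE4, and Med6_WT for Med6_delH1. Both stresses were compared with the same no_stress libraries. Med15_Taf1, Med15_Med16, Med2_15 and Med1_5 had both named factors tagged per the labels. Per the genotype labels, the Med7C, Med7N and TID strains made a subunit as separate parts from plasmids, with the degron on the named part, and the Med14C strain carried degrons on MED14 and on a plasmid copy beside a second partial copy. The genotype label of the Med31 libraries named the degron on MED19, unlike their titles, and the titles were followed. Differences between changes were fitted with limma as a difference of differences over the libraries of both comparisons, and with edgeR for Med15 under HS against Med15 under SM.

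Replicate letters were taken to pair treated and control libraries where the deviations of same-letter libraries from their group means correlated at over 0.1 in every pair, with at least 3 pairs. Med21_EWE4, with 2 pairs at 0.32, was not counted. This held in 15 of the 32 comparisons: CCL1, Med5, Med2_15, Med7C, Med10, Med14, Med14C, TID, Med15, Med15_Med16, Med15_Taf1, Med16, Med17 and Med15 under HS and under SM. The labels do not say what a letter marks.

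The libraries named in the design, controls, gene lists and rule for named genes were set before the data were examined. So were the tests, except limma where reads were recovered. In the main comparisons (Med14, Med17, Med15, Med16, CDK8, CCL1, Med15_Taf1, med15del and the 4 stress comparisons), the rule named the 5 largest rises and the 5 largest falls by log2 change of signal plus 1 (edgeR's log2 change for counts). Order between genes is by that measure, and folds (ratios of mean levels) can order them differently. In others it named 2 and 2. A named gene had an adjusted p under 0.05, a mean of at least 50 in the higher group and no overlap between the libraries of the groups. The targeted gene came first in each comparison whatever its p, and marker genes of the strains, transposon genes and dubious reading frames were left out. A gene that the rule named is not reported here.

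The lists were cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, the seripauperin family, ribosome biogenesis, amino acid biosynthesis (Gcn4 targets), Hsf1 chaperone targets, Msn2/4 stress genes, glycolysis, the phosphate regulon, pheromone response and alpha-specific genes, a-specific genes as markers of another mating type, Mediator subunits, the proteasome, core histones, the iron regulon, hexose transporters, flocculins and cell surface, drug efflux and detoxification, methionine and sulfur assimilation, ergosterol synthesis, respiration, and RNA polymerase II and general factors. They were written from background knowledge, not these libraries. Each was compared with all other genes tested by camera with a preset correlation of 0.01, adjusted over the 22 lists. Of 676 list tests, 367 passed at 0.05, and 9 passed with an estimated correlation in place of the preset one. These 9 were methionine and sulfur assimilation in CDK8 and med7N_del, glycolysis in Med2_15 and Med15 under HS, core histones in Med2_15, drug efflux in Med2_15, med15del and Med15 under HS, and amino acid biosynthesis in SM in DMSO.

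Promoters with a TATA box were those with the sequence TATA(A/T)A(A/T)(A/G) between 50 and 250 bp upstream of the coding start in the reference genome, which held for 1373 of 5792 genes. Their median log2 change was compared with that of other genes by a two-sided permutation test with 100000 resamples, adjusted over the 32 comparisons. Overlaps of changed genes, added after the data were examined, were tested with Fisher's exact test, one-sided, over genes tested in both comparisons. This test counts genes as independent, though some change together, so its p-values overstate the evidence.

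Data with known changes were run through the same steps. Gene calls were checked on sets simulated with a dispersion (replicate spread beyond counting noise) of 0.02. The numbers of unchanged genes called hold for that setting only. In the real Med16 libraries, another division into 3 and 3 called 309 genes. In 1 such set made from the Med16 libraries (4859 genes), limma called 54 of 97 genes changed by 1.5-fold and 99 of 100 changed by 2-fold, with 2 unchanged genes called. Made from the Med1 libraries (4698 genes), the calls were 50 of 97 and 96 of 96, with 7 unchanged genes. For HS in DMSO (5522 genes), edgeR called 51 of 100 and 98 of 100, with 7 unchanged genes. The difference of Med1_5 against Med5 (4832 genes) called 13 of 99 and 70 of 100, with 6 unchanged genes. A 4-fold fall put on all genes of Med16 (4564 genes) gave a median of −1.92 and 4564 falls with limma, and with TMM scaling a median of −0.00 and 68 falls over 4352 genes. With camera over 22 lists, a shifted list was called in 10 of 10 runs and 0 lists without a shift. The TATA test made 0 calls in 40 simulations without a shift and 40 with a shift of 0.1. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.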

Results

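The libraries measured RNA made in a 5 min labelling window in budding yeast after depletion, deletion or mutation of subunits of Mediator, the complex that links transcription activators to RNA polymerase II. They address how far each part of Mediator is needed for new transcription of each gene. For the typical gene, the deposited signal fell most after depletion of Med15 with Taf1, a subunit of the general factor TFIID (median log2 change −2.50), of Ccl1, the cyclin of the general factor TFIIH (−2.18), of the Mediator subunit Med10 (−2.13) and of Med14, the scaffold subunit (−1.96). After depletion of Med15 or Med16, both of the Mediator tail, the medians were 0.07 and 0.06. After depletion of CDK8 or Med12 of the kinase module they were −0.01 and 0.06. With TMM scaling, which takes the typical gene as unchanged, the medians of the 28 comparisons lay between −0.09 and 0.06, so each change given below shifts by about the median of its comparison.

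**Figure D1:**
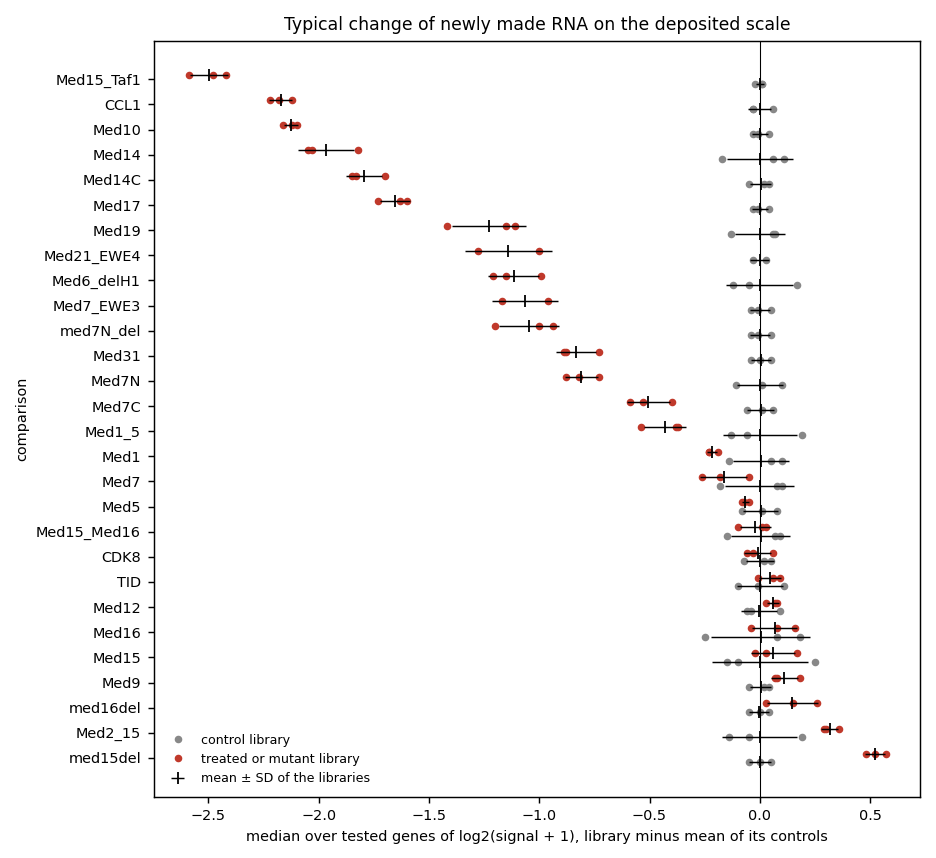
Median log2 change of each treated or mutant library (points) and of each control library (points) relative to the mean of the controls, on the deposited scale, for 28 comparisons, with mean ± SD of the libraries as bars. The medians run from −2.50 (Med15_Taf1) to 0.52 (med15del).

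After depletion of Ccl1, CCL1 itself (YPR025C, coding region on chromosome XVI from 613377 to 614558 in the sacCer3 build of the reference annotation, as for all coordinates here) had a signal of 11.9 ± 1.44 against 45.4 ± 3.39 (mean ± SD, n = 3 libraries each), a log2 change of −1.85 ± 0.10 that was less negative than that of the typical gene and became 0.33 with TMM scaling. HSP82 (XVI, 96496 to 98625), which codes for the heat-inducible chaperone Hsp90, fell 56.7-fold, from 465 ± 78.4 to 8.2 ± 0.966 (limma adjusted p = 7.7e-14). The chaperone genes HSP42 (−5.34 ± 0.11), SSA1 (−5.14 ± 0.11) and STI1 (−4.72 ± 0.10) and MF(ALPHA)1, which codes for the alpha-factor pheromone (−4.72 ± 0.19), were the other largest falls. PDR12 (XVI, 445842 to 450377), a transporter gene for weak acids, rose from 45.5 ± 15.2 to 104 ± 26.4 (log2 change 1.20 ± 0.22, adjusted p = 9.78e-05). All 24 tested Hsf1 chaperone targets fell (24 adjusted over the list alone), with a median of −3.87, or −1.68 with TMM scaling (camera adjusted p = 3.05e-08, and adjusted p = 0.556 with an estimated correlation). The 80 tested ribosome biogenesis genes fell by less than the typical gene, with a median of −1.36 that flips to 0.85 with TMM scaling (80 falls, 80 adjusted over the list alone, camera adjusted p = 3.03e-10, and adjusted p = 0.573 with an estimated correlation). The 122 tested cytoplasmic ribosomal protein genes had a median of −1.48, which flips to 0.69 with TMM scaling (122 falls, 122 adjusted over the list alone, camera adjusted p = 5.38e-13, and adjusted p = 0.556 with an estimated correlation). Of 3927 genes tested, limma called 3 higher and 3921 lower, 3828 of them by more than 2-fold; TMM scaling gave 1395 higher and 1218 lower.

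After depletion of Med14, RGR1, the gene of Med14 (YLR071C, XII, 275378 to 278626), fell from 85.7 ± 7.44 to 28.5 ± 3.76, a log2 change of −1.56 ± 0.17 that became 0.49 with TMM scaling. The pheromone gene MF(ALPHA)1 fell 31.8-fold, from 249 ± 43.8 to 7.84 ± 0.607 (limma adjusted p = 3.6e-22). Falls of like size were in PRY3 (log2 change −4.72), HSP82 (−4.58), STE3, the gene of the a-factor receptor (−4.55), and DSE2, a gene of the daughter cell wall (−4.54). NRD1 (YNL251C, XIV, 172588 to 174315), which codes for an RNA-binding protein of early transcription termination, rose 3.11-fold, from 39.7 ± 2.42 to 123 ± 29.6 (log2 change 1.59 ± 0.18, adjusted p = 1.84e-10). SER3, of serine synthesis (1.39 ± 0.16), and HRP1, of RNA 3′-end formation (1.39 ± 0.19), were the other rises. All 24 tested Hsf1 targets fell (24 adjusted over the list alone, median −2.92, and −1.05 with TMM scaling, camera adjusted p = 2.44e-07, and adjusted p = 0.617 with an estimated correlation), as did all 14 drug efflux genes (14 adjusted over the list alone, median −2.93, and −0.70 with 9 falls and 2 rises with TMM scaling, camera adjusted p = 0.00223, and adjusted p = 0.617 with an estimated correlation). Ribosome biogenesis genes fell by less than the typical gene (81 of 81, also 81 adjusted over the list alone), with a median of −1.19 that flips to 0.85 with TMM scaling, where 75 rose (camera adjusted p = 7.9e-20, and adjusted p = 0.617 with an estimated correlation). RNA polymerase II and general factor genes fell in 35 of 35 cases (35 adjusted over the list alone), with a median of −1.64 that flips to 0.38 with TMM scaling (camera adjusted p = 0.0331, and adjusted p = 0.926 with an estimated correlation). The 14 tested Mediator subunit genes had a median of −1.94 (camera adjusted p = 0.903). Of 3543 genes tested, limma called 3 higher and 3533 lower. TMM scaling gave 1053 and 810, and without the filter 5361 genes changed.

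The Med14C strain carried degrons on Med14 beside a partial copy. The signal of RGR1, to which plasmid copies add, fell from 1270 ± 68.3 to 423 ± 34.5, a log2 change of −1.58 ± 0.09 that became 0.30 with TMM scaling. FMP48 fell 40.8-fold and MF(ALPHA)2 24-fold (log2 changes −4.56 ± 0.10 and −4.41 ± 0.08), while PDR12 (1.14 ± 0.08) and NRD1 (0.34 ± 0.08) rose. All 24 Hsf1 targets fell (24 adjusted over the list alone, median −2.69, and −0.91 with TMM scaling, camera adjusted p = 9.9e-27, and adjusted p = 0.434 with an estimated correlation). Of 4220 genes, limma called 4 higher and 4216 lower, and with TMM scaling 1415 and 1189. After depletion of the separate tail-interacting part of Med14 (TID), RGR1 had 1280 ± 177 against 1135 ± 272 (log2 change 0.19 ± 0.19, limma adjusted p = 0.681). ZRT1, the high-affinity zinc transporter gene, fell 4.58-fold to 64.3 ± 1.51 (log2 change −2.16 ± 0.15, adjusted p = 2.51e-05), and MF(ALPHA)2 had −1.81 ± 0.26. YMC2, of the mitochondrial carriers (0.82 ± 0.14), and RRP46, of the RNA exosome (0.76 ± 0.13), rose. Glycolysis genes fell in 14 of 16 cases (16 adjusted over the list alone, median −1.21, camera adjusted p = 1.63e-26, and adjusted p = 0.118 with an estimated correlation). Limma called 41 of 4755 genes higher and 231 lower, 272 in all. Replicate letters as a block gave 1084 and turned the balance, with 596 higher and 488 lower. The count was 181 without 3IAA B, 176 without 3IAA C, 502 without DMSO A and 149 without DMSO B; without DMSO B the calls of YMC2, RRP46 and MF(ALPHA)2 were lost.

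After depletion of Med17, of the Mediator head, its gene SRB4 (YER022W, V, 198812 to 200875) fell from 43.5 ± 1.88 to 12.8 ± 0.775 (log2 change −1.69 ± 0.09, and −0.02 and not called with TMM scaling). The largest falls were in BTN2, of protein sorting under stress (−3.80 ± 0.13, a 14.2-fold fall), HSP42 (−3.72), HSP82 (−3.43, from 632 ± 24.1 to 58 ± 7.02), GPD1, of glycerol synthesis (−3.33), and ROQ1, of stress-induced protein breakdown (−3.27). NRD1 rose 2.31-fold, from 141 ± 34.1 to 325 ± 7.19 (1.23 ± 0.11, limma adjusted p = 2.11e-11). All 24 Hsf1 targets fell (24 adjusted over the list alone, median −2.50, and −0.75 with TMM scaling, camera adjusted p = 5.1e-10, and adjusted p = 0.734 with an estimated correlation). Of 3974 genes, limma called 4 higher and 3963 lower, and with TMM scaling 1169 and 888. After depletion of Med10, its gene NUT2 was under the filter on low signal (1.35 ± 0.238 against 5.95 ± 0.194). HSP82 fell 58.5-fold (−5.74 ± 0.10) and INO1, of inositol synthesis, 39.9-fold (−5.26 ± 0.19), while HRP1 (1.37 ± 0.06) and NRD1 (1.36 ± 0.05, from 143 ± 3.92 to 367 ± 4.53) rose. Its 24 Hsf1 targets fell with a median of −3.59, or −1.46 with TMM scaling (24 adjusted over the list alone, camera adjusted p = 2.16e-05, and adjusted p = 0.83 with an estimated correlation). Of 4455 genes, limma called 5 higher and 4446 lower, and with TMM scaling 1579 and 1430.

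After depletion of Med15 with Taf1, the gene of Med15, GAL11, fell from 444 ± 20.4 to 83.8 ± 2.73 and TAF1 (YGR274C, VII, 1039895 to 1043095) from 163 ± 7.42 to 31.6 ± 2.08. Their log2 changes of −2.39 ± 0.08 and −2.33 ± 0.08 became 0.22 and 0.26 with TMM scaling. MF(ALPHA)2 fell 158-fold, from 238 ± 18.9 to 1.51 ± 0.307 (log2 change −6.58 ± 0.09). ALD6, the main cytosolic acetaldehyde dehydrogenase gene, fell 46.5-fold (−5.51), and INO1 (−5.35), BTN2 (−5.22) and the cell wall gene CWP1 (−5.21) also fell. NRD1 rose 5.84-fold, from 259 ± 20.6 to 1514 ± 126 (2.54 ± 0.09, limma adjusted p = 1.4e-31), and SER3 (1.93 ± 0.09) and HRP1 (0.47 ± 0.08) also rose. All 24 Hsf1 targets fell (24 adjusted over the list alone, median −3.59, and still below all genes with TMM scaling, camera adjusted p = 3.85e-11, and adjusted p = 0.706 with an estimated correlation). Ribosome biogenesis genes fell in 81 of 81 cases (81 adjusted over the list alone), with a median of −2.06 that flips to 0.51 with TMM scaling (camera adjusted p = 0.00146, and adjusted p = 0.941 with an estimated correlation). Of 4688 genes, limma called 3 higher and 4684 lower, 4666 by more than 2-fold; TMM scaling gave 1771 higher and 1449 lower. Compared with depletion of Med15 alone, the changes of 4564 of 4572 genes differed (median difference −2.56); with TMM scaling 2112 differed, 1202 more positive and 910 more negative. The difference was −5.81 ± 0.27 in BTN2 and −4.55 ± 0.22 in the glutathione transferase gene ECM4, and it was 2.43 ± 0.20 in NRD1 and 2.29 ± 0.21 in SER3.

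**Figure D2:**
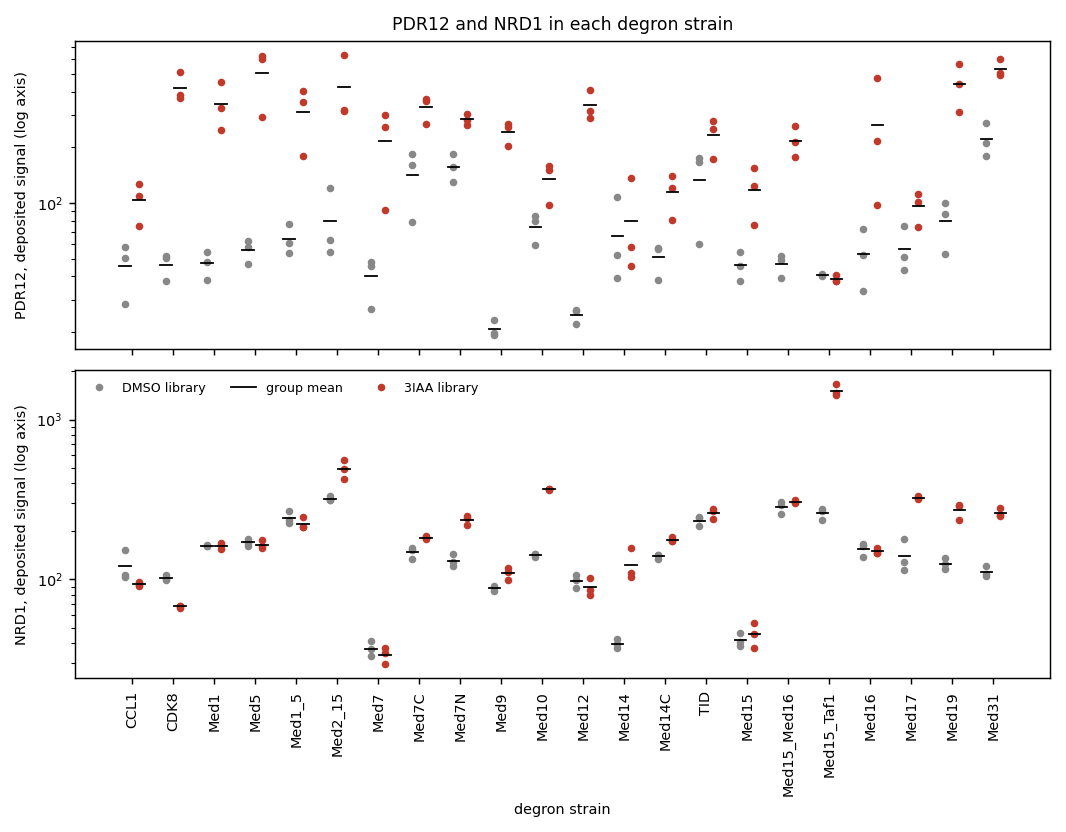
Signal of PDR12 and NRD1 in each 3IAA and DMSO library of the 22 degron strains, on a log axis in the authors' units of signal, with 1 point per library and a bar at the group mean. PDR12 rose from 24.8 ± 2.4 to 337 ± 61.5 after Med12 depletion, and NRD1 from 259 ± 20.6 to 1514 ± 126 after depletion of Med15 with Taf1 (mean ± SD).

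After depletion of Med19, its gene ROX3 fell from 56.9 ± 6.84 to 21.1 ± 1.63 (log2 change −1.39 ± 0.15, and −0.15 and not called with TMM scaling). BTN2 fell 17.3-fold (−4.01 ± 0.15) and HSP82 14.4-fold (−3.89 ± 0.15), while PDR12 rose 5.51-fold (2.46 ± 0.15) and HXT1, a low-affinity glucose transporter gene, rose (1.21 ± 0.15). All 24 Hsf1 targets fell (24 adjusted over the list alone, median −2.39, and −1.14 with TMM scaling, camera adjusted p = 8.62e-57, and adjusted p = 0.296 with an estimated correlation). Glycolysis genes fell by less than the typical gene, 10 of 16 of them with 2 rises (10 and 2 adjusted over the list alone), and their median of −0.33 flips to 0.93 with TMM scaling (camera adjusted p = 1.32e-16, and adjusted p = 0.404 with an estimated correlation). Of 4476 genes, limma called 22 higher and 4374 lower, and with TMM scaling 977 and 826. In the libraries titled Med31, SOH1, the gene of Med31, fell from 35.1 to 15.9 (−1.09 ± 0.10). TIS11, an mRNA decay gene of the iron response, fell 8.08-fold (−2.94 ± 0.16) and FET3, of iron uptake, 6.94-fold (−2.83 ± 0.19). PDR12 (1.28 ± 0.12) and NRD1 (1.22 ± 0.09) rose. Iron regulon genes fell in 13 of 13 cases (13 adjusted over the list alone, median −1.87, and −1.07 with TMM scaling, camera adjusted p = 0.0066, and adjusted p = 0.802 with an estimated correlation). Of 4563 genes, limma called 15 higher and 4440 lower, and with TMM scaling 831 and 892.

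After depletion of Med7, of the Mediator middle, MED7 had a log2 change of −0.31 ± 0.20 (limma adjusted p = 0.439). INO1 fell from 247 ± 137 to 40.8 ± 23.3 (−2.58 ± 0.28) and the glycine cleavage gene GCV1 also fell (−2.01 ± 0.19), while PDR12 (2.28 ± 0.23) and the cell wall gene TIP1 (0.62 ± 0.18) rose. Genes of glycolysis fell in 14 of 16 cases (14 adjusted over the list alone, median −0.82, camera adjusted p = 7.6e-13, and adjusted p = 0.322 with an estimated correlation). Of 4027 genes, limma called 8 higher and 363 lower, 371 in all, and with TMM scaling 57 and 238. The count was 227 without 3IAA C, 178 without DMSO B and 612 without DMSO C, and the call of TIP1 was lost without 3IAA A, B or C or DMSO C. In the Med7C strain, MED7 had 0.09 ± 0.10 (limma adjusted p = 0.396; 0.61 and called with TMM scaling). INO1 (−2.39 ± 0.26) and TIS11 (−2.26 ± 0.36, not called with TMM scaling) fell, and PDR12 (1.30 ± 0.17) and NRD1 (0.30 ± 0.10) rose. Msn2/4 stress genes fell in 23 of 23 cases (23 adjusted over the list alone, median −1.39, and −0.89 with TMM scaling, camera adjusted p = 7.76e-19, and adjusted p = 0.593 with an estimated correlation). Limma called 8 of 4526 genes higher and 4311 lower, and with TMM scaling 414 and 668. In the Med7N strain, MED7 fell (−0.74 ± 0.10, and 0.10 with TMM scaling), INO1 fell 6.79-fold to 48.4 ± 7.5 (−2.75 ± 0.10) and HSP82 fell (−2.29 ± 0.10), while PDR12 (0.87 ± 0.10) and NRD1 (0.84 ± 0.10) rose. All 24 Hsf1 targets fell (24 adjusted over the list alone, median −1.38, and −0.53 with TMM scaling, camera adjusted p = 1.87e-28, and adjusted p = 0.412 with an estimated correlation). Limma called 12 of 4262 genes higher and 4226 lower, and with TMM scaling 934 and 830.

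After depletion of Med15, GAL11 (YOL051W, XV, 234940 to 238185) had a signal of 107 ± 20.3 against 102 ± 13.7 (log2 change 0.06 ± 0.19, limma adjusted p = 0.997). ALD6 (YPL061W, XVI, 432588 to 434090) fell 6.47-fold, from 678 ± 143 to 105 ± 13.7 (−2.67 ± 0.20, adjusted p = 3.81e-38). ZRT1 (−2.12 ± 0.20), MF(ALPHA)1 (−2.11), INO1 (−2.05) and DSE2 (−1.94) were the next falls. PDR12 rose 2.56-fold, from 45.9 ± 8.41 to 117 ± 39.7 (1.29 ± 0.19), and the other rises were YAT2, of carnitine transfer (1.14), SAM4, of methionine metabolism (0.86), ARG7, of arginine synthesis (0.83), and ARO3, of aromatic amino acid synthesis (0.65). Glycolysis genes fell in 16 of 16 cases (16 adjusted over the list alone, median −1.32, camera adjusted p = 3.59e-55, and adjusted p = 0.0801 with an estimated correlation). Iron regulon genes fell in 12 of 17 (12 adjusted over the list alone, median −0.83, camera adjusted p = 3.33e-22, and adjusted p = 0.203 with an estimated correlation), hexose transporter genes in 3 of 4 (3 adjusted over the list alone, median −1.54, camera adjusted p = 1.19e-14, and adjusted p = 0.0801 with an estimated correlation) and flocculin and cell surface genes in 4 of 5 (4 adjusted over the list alone, camera adjusted p = 4.25e-09, and adjusted p = 0.203 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of 0.14, with 0 of 54 called by limma (0 adjusted over the list alone, camera adjusted p = 0.0477, and adjusted p = 0.912 with an estimated correlation). The 1 tested a-specific gene had −0.03 (camera adjusted p = 0.853). Of 4088 genes, limma called 27 higher and 182 lower, 209 in all, and with TMM scaling 93 and 281. The count was 133 without 3IAA C and 648 without DMSO A; the call of ARO3 was lost with replicate letters as a block and without 3IAA A or C or DMSO B or C, and that of ARG7 without DMSO B.

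After depletion of Med2 with Med15, MED2 and GAL11 rose (0.56 ± 0.13 and 0.43 ± 0.11), and neither was called with TMM scaling (0.24 and 0.11). GAL11 was also not called without DMSO B. GRE2, a stress-induced reductase gene, fell 3.81-fold, from 1294 ± 116 to 340 ± 41.4 (−1.93 ± 0.12), and MF(ALPHA)2 fell 4.68-fold (−2.17 ± 0.16). ATO2, an ammonia transporter gene, rose from 7.57 ± 3.4 to 55.7 ± 40.1 (2.57 ± 0.34), and PDR12 also rose (2.40 ± 0.25). Genes of glycolysis fell in 15 of 16 cases (15 adjusted over the list alone, median −1.14, camera adjusted p = 1.45e-55), and drug efflux genes in 10 of 18 with 3 rises (10 and 3 adjusted over the list alone, median −0.51, camera adjusted p = 3.71e-23). Limma called 2293 of 5140 genes higher and 176 lower, 2469 in all, and with TMM scaling 183 and 364; replicate letters as a block gave 3743. The count was 1254 without 3IAA A, 1211 without 3IAA B, 1196 without 3IAA C, 696 without DMSO A, 850 without DMSO B and 4397 without DMSO C.

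After depletion of Med16, its gene SIN4 had 118 ± 5.99 against 119 ± 15.2 (log2 change −0.00 ± 0.18, limma adjusted p = 0.999). PDR12 had 263 ± 194 against 52.6 ± 19.6 (2.08 ± 0.18, adjusted p = 2.14e-28, or 0.0471 with TMM scaling). The transcription factor gene CIN5 rose from 70 ± 4.71 to 209 ± 33.8 (1.55), and STP4 (1.70), HOR7 (1.33) and HAP4, a regulator of respiration (1.04), also rose. ARG80, a regulator of arginine metabolism, fell 2.84-fold, from 89.7 ± 11.9 to 31.6 ± 2.92 (−1.47 ± 0.17). DSE2 (−1.36), YCR102C (−1.19), PRY3 (−1.08) and YLR460C (−1.06) followed. Stress genes of the Msn2/4 list rose in 5 of 19 cases (9 adjusted over the list alone, 12 with replicate letters as a block, 1 with TMM scaling, median 0.40, camera adjusted p = 3.38e-10, and adjusted p = 0.505 with an estimated correlation). Phosphate regulon genes fell in 3 of 13 (4 adjusted over the list alone, 6 with the block, 6 with TMM scaling, median −0.28, camera adjusted p = 3.36e-10, and adjusted p = 0.505 with an estimated correlation). Of 4871 genes, limma called 57 higher and 57 lower, 114 in all, and with TMM scaling 91 and 176. Replicate letters as a block gave 390 higher and 219 lower, 609 in all, so the balance depended on the setting. The count was 75 without 3IAA A, 62 without 3IAA B and 68 without DMSO B; the call of STP4 was lost with TMM scaling, and those of PDR12, STP4 and HAP4 without DMSO C.

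After depletion of Med15 with Med16, GAL11 had −0.16 ± 0.13 (limma adjusted p = 0.417; −0.15 and called with TMM scaling) and SIN4 0.07 ± 0.12 (adjusted p = 0.725). ZRT1 fell 5.03-fold (−2.33 ± 0.13) and FET3 4.57-fold (−2.20 ± 0.13), while ATO2 rose 8.51-fold (2.88 ± 0.14) and PDR12 rose (2.19 ± 0.12). Glycolysis genes fell in 16 of 16 cases (16 adjusted over the list alone, median −1.53, camera adjusted p = 1.9e-41, and adjusted p = 0.128 with an estimated correlation), and core histone genes in 8 of 8 (8 adjusted over the list alone, median −1.15, camera adjusted p = 5.7e-13, and adjusted p = 0.128 with an estimated correlation). Cytoplasmic ribosomal protein genes fell in 122 of 138 (132 adjusted over the list alone, median −0.43, camera adjusted p = 8.9e-18, and adjusted p = 0.485 with an estimated correlation). Msn2/4 stress genes rose in 19 of 25, with 1 fall (20 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 4.64e-15, and adjusted p = 0.454 with an estimated correlation). Limma called 570 of 5085 genes higher and 810 lower, 1380 in all, 2185 with TMM scaling, 2420 with replicate letters as a block and 788 without 3IAA A.

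After depletion of CDK8, the kinase of the Mediator kinase module, its gene SSN3 had 48.8 ± 2.99 against 47.2 ± 3.24 (log2 change 0.05 ± 0.08, limma adjusted p = 0.769). PDR12 rose 9.08-fold, from 46.4 ± 7.55 to 421 ± 76.6 (3.15 ± 0.13, adjusted p = 1.99e-08), followed by STP4 (2.05), the kinase gene FMP48 (2.03), the stress-induced cell wall gene YGP1 (1.93) and CIN5 (1.83). MET6, methionine synthase, fell 3.21-fold, from 230 ± 10.8 to 71.8 ± 2.98 (−1.67 ± 0.07). SHM2 and GCV2, of one-carbon metabolism (−1.61 and −1.23), the iron-binding cell wall gene FIT1 (−1.17) and SAM2, of S-adenosylmethionine synthesis (−1.08), also fell. Methionine and sulfur genes fell in 13 of 18 cases with 1 rise (15 and 1 adjusted over the list alone, median −0.51, camera adjusted p = 2.51e-13). Hsf1 targets fell in 21 of 24 (21 adjusted over the list alone, median −0.47, camera adjusted p = 5.47e-17, and adjusted p = 0.256 with an estimated correlation). Ergosterol genes fell in 13 of 22 (15 adjusted over the list alone, median −0.35, camera adjusted p = 3.98e-11, and adjusted p = 0.224 with an estimated correlation). Core histone genes rose in 8 of 8 (8 adjusted over the list alone, median 0.62, camera adjusted p = 9.93e-11, and adjusted p = 0.224 with an estimated correlation), and Msn2/4 stress genes in 14 of 23 (19 adjusted over the list alone, median 0.53, camera adjusted p = 1.92e-14, and adjusted p = 0.224 with an estimated correlation). Of 4592 genes, limma called 346 higher and 226 lower.

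After depletion of Med12, of the same module, SRB8 had 0.29 ± 0.08 (limma adjusted p = 0.0354), a call lost with TMM scaling and without any of 3IAA A, B or C or DMSO B or C. PDR12 rose 13.6-fold, from 24.8 ± 2.4 to 337 ± 61.5 (3.70 ± 0.12, adjusted p = 2.08e-09), and SRX1, of the oxidative stress response, also rose (2.08 ± 0.08). MET6 fell 4.22-fold (−2.04 ± 0.09), and SHM2 had −1.80 ± 0.15. Stress genes of the Msn2/4 list rose in 20 of 20 cases (20 adjusted over the list alone, median 0.91, camera adjusted p = 1.88e-16, and adjusted p = 0.282 with an estimated correlation). Ribosome biogenesis genes fell in 24 of 81 (44 adjusted over the list alone, 68 with TMM scaling, median −0.23, camera adjusted p = 8.5e-23, and adjusted p = 0.282 with an estimated correlation). Limma called 561 of 4481 genes higher and 217 lower, 778 in all, and with TMM scaling 441 and 646. The count was 379 without 3IAA A, 377 without 3IAA B, 511 without 3IAA C and 1223 without DMSO A. CDK8 and Med12 shared 201 rises, where 41 would be shared if the calls were independent, and 96 falls against 10.9 (Fisher's exact test, one-sided, adjusted p = 1.91e-108 and 2.23e-73). The likeness was not particular to this module. Across genes, the log2 changes of CDK8 had a Pearson correlation of 0.75 with Med12, 0.72 with Med1, 0.70 with Med5 and −0.06 with Med14. Every treated degron culture received 3IAA, and its part in these shared changes was not tested.

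After depletion of Med1, MED1 had 82.9 ± 6.8 against 84.2 ± 6.32 (log2 change −0.02 ± 0.11, limma adjusted p = 0.852). PDR12 rose 7.26-fold, from 47 ± 8.01 to 341 ± 102 (2.81 ± 0.12), and SRX1 rose from 47.5 ± 3.65 to 115 ± 3.48 (1.27 ± 0.10). FIT1 (−1.25 ± 0.10) and BTN2 (−1.19 ± 0.12) fell. Hsf1 targets fell in 24 of 24 cases (24 adjusted over the list alone, median −0.57, and −0.36 with TMM scaling, camera adjusted p = 7.2e-22, and adjusted p = 0.282 with an estimated correlation). Hexose transporter genes rose in 4 of 5 (4 adjusted over the list alone, median 0.32, camera adjusted p = 8.04e-13, and adjusted p = 0.0538 with an estimated correlation). Limma called 86 of 4703 genes higher and 1701 lower, 1787 in all, and with TMM scaling 221 and 101. The count was 735 without 3IAA A, 874 without 3IAA B, 599 without 3IAA C, 511 without DMSO A, 468 without DMSO B and 3761 without DMSO C.

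After depletion of Med5, its gene NUT1 had 0.10 ± 0.08 (limma adjusted p = 0.605). PDR12 rose 9.07-fold, from 55.6 ± 7.83 to 504 ± 183 (3.09 ± 0.22, adjusted p = 2.85e-05), and YGP1 rose (1.04 ± 0.11). MET6 fell (−0.69 ± 0.08), and SAM1, of S-adenosylmethionine synthesis, had −0.74 ± 0.13, a call lost with TMM scaling and without 3IAA B, 3IAA C, DMSO A or DMSO B. Hsf1 targets fell in 2 of 24 cases (22 adjusted over the list alone, 23 with replicate letters as a block, 1 with TMM scaling, median −0.35, camera adjusted p = 1.84e-15, and adjusted p = 0.369 with an estimated correlation). Limma called 26 of 4851 genes higher and 8 lower, 34 in all, and with TMM scaling 34 and 3. Replicate letters as a block gave 484 and turned the balance, with 132 higher and 352 lower. A pseudocount of 0.1 with a lower filter gave 53 and edgeR on recovered reads 63. The count was 166 without 3IAA A, 15 without 3IAA B, 14 without 3IAA C and 15 without DMSO B. After depletion of Med1 with Med5, MED1 (−0.63 ± 0.15) and NUT1 (−0.48 ± 0.16) fell, and neither was called with TMM scaling (−0.19 and −0.05); NUT1 was also not called without 3IAA C. PDR12 rose 4.9-fold (2.21 ± 0.16) and SRX1 rose (1.41), while FIT1 (−1.56 ± 0.16) and the heme oxygenase gene HMX1 (−1.56 ± 0.15) fell. Hsf1 targets fell in 24 of 24 (24 adjusted over the list alone, median −0.87, and −0.44 with 6 falls with TMM scaling, camera adjusted p = 1.5e-24, and adjusted p = 0.191 with an estimated correlation). Limma called 32 of 4781 genes higher and 3729 lower, 3761 in all, 1795 without 3IAA C, and with TMM scaling 161 higher and 52 lower.

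After depletion of Med9, its gene CSE2 was under the filter on low signal (1.66 ± 0.292 against 1.66 ± 0.181). PDR12 rose 11.6-fold, from 20.8 ± 2.05 to 242 ± 34.9 (3.47 ± 0.09), and SRX1 4.68-fold (2.20 ± 0.08). The iron genes FIT2 (−0.89 ± 0.15) and FTR1 (−0.85 ± 0.10) fell. Msn2/4 stress genes rose in 22 of 23 cases (22 adjusted over the list alone, median 0.63, camera adjusted p = 1.13e-09, and adjusted p = 0.555 with an estimated correlation). Ribosome biogenesis genes fell in 39 of 80 with 1 rise (39 and 1 adjusted over the list alone, 72 and 0 with TMM scaling, median −0.15, camera adjusted p = 1.3e-20, and adjusted p = 0.555 with an estimated correlation). Limma called 1519 of 4058 genes higher and 383 lower, and with TMM scaling 939 and 1111.

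**Figure D3:**
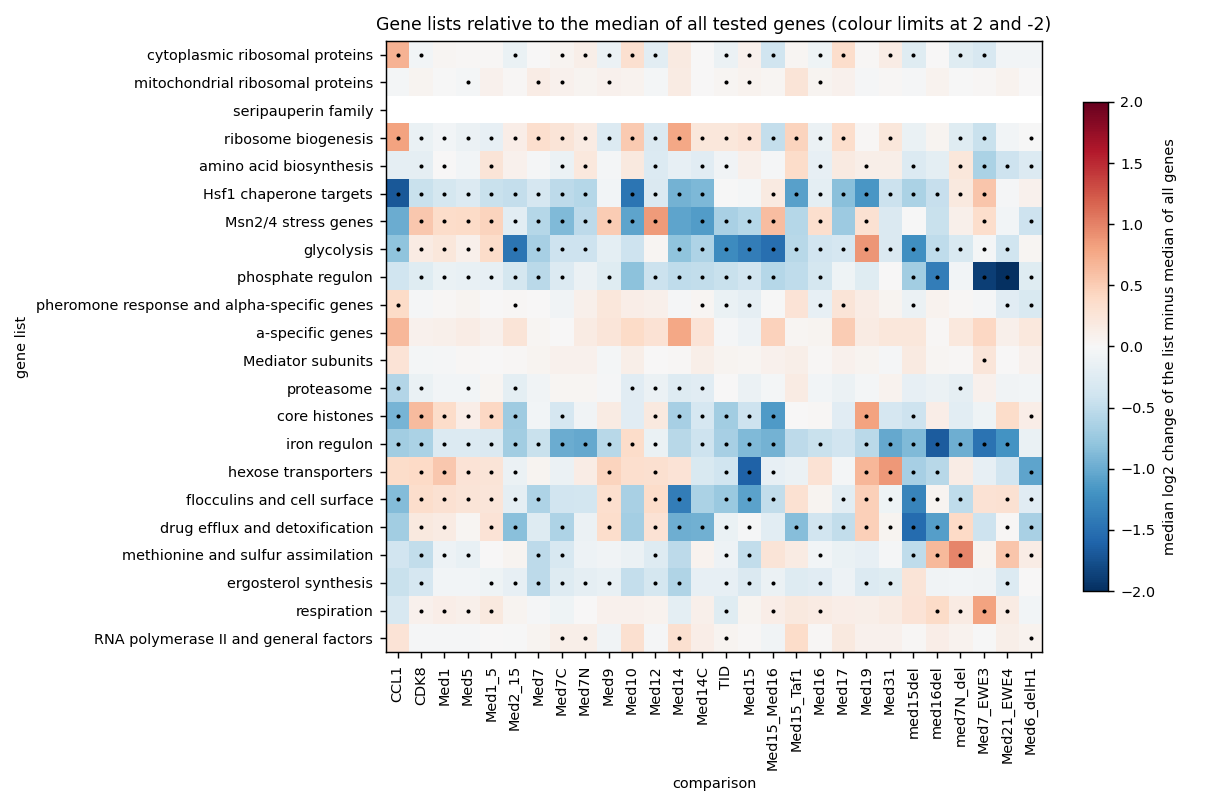
Median log2 change of each of the 22 gene lists minus the median of all genes tested, for 28 comparisons on the deposited scale. The colour gives the value, and a dot marks a camera adjusted p under 0.05 in either direction. Camera uses a different statistic from the median, so its direction can oppose the colour. After Med10 depletion the Msn2/4 genes had a median of −3.19, below all genes, while camera gave a shift up (camera adjusted p = 0.00151). After Ccl1 depletion the Hsf1 targets lie below all genes (median −3.87 against −2.18), and the seripauperin family is blank because no member passed the filter on low signal.

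In the strain without Med15 (med15del), GAL11 had 0.803 ± 0.215 against 81 ± 2.13 (log2 change −5.51 ± 0.09). GRE2 fell 27.1-fold, from 214 ± 6.51 to 7.92 ± 1.82 (−4.61 ± 0.12, limma adjusted p = 3.34e-11). The drug pump genes PDR5 (−3.89, a 15.5-fold fall), TPO1 (−3.04) and FLR1 (−2.84) and the pheromone gene MF(ALPHA)1 (−2.60) also fell. GSC2, a glucan synthase gene of the cell wall, rose 4.72-fold, from 19.9 ± 0.507 to 94 ± 6.9 (2.18 ± 0.07), as did the zinc regulator gene ZAP1 (2.16), MCT1 (2.10), TIP1 (1.87) and BUR6 (1.68). Drug efflux genes fell in 12 of 17 cases with 2 rises (12 and 2 adjusted over the list alone, 16 and 0 of 16 with TMM scaling, median −1.02, camera adjusted p = 1.78e-35). Genes of glycolysis fell in 10 of 14 (10 adjusted over the list alone, median −0.70, camera adjusted p = 7.38e-28, and adjusted p = 0.11 with an estimated correlation). Of 3179 genes, limma called 2786 higher and 168 lower (median 0.52), and with TMM scaling 468 and 1076 (median −0.09). Without the filter 5180 genes changed, and 4716 with a pseudocount of 0.1 and a lower filter. Compared with Med15 depletion, the changes of 2014 of 3840 genes differed, 1947 of them more positive in med15del, and with TMM scaling 956 differed, 279 of them more positive. The difference was −3.45 ± 0.21 in GRE2 and −2.95 ± 0.20 in FLR1, and 4.48 ± 0.28 in ARO10 and 2.45 ± 0.21 in ZRT1. In the strain without Med16 (med16del), SIN4 had 0.143 ± 0.0231 against 24.4 ± 0.884. The proline permease gene PUT4 rose from 0.393 ± 0.116 to 59.2 ± 3.99, and the flocculin gene FLO11 from 3.89 ± 0.367 to 231 ± 122. The phosphate transporter gene PHO84 fell 10.6-fold (−3.31 ± 0.11) and PDR5 7.37-fold (−2.86 ± 0.12). Iron regulon genes fell in 13 of 15 with 2 rises (13 and 2 adjusted over the list alone, median −1.51, camera adjusted p = 3.28e-28, and adjusted p = 0.149 with an estimated correlation), and phosphate regulon genes in 8 of 8 (8 adjusted over the list alone, median −1.24, camera adjusted p = 8.57e-18, and adjusted p = 0.149 with an estimated correlation). Limma called 813 of 2813 genes higher and 248 lower, and with TMM scaling 367 and 764. Without the filter 2501 genes changed, and 2262 with a pseudocount of 0.1 and a lower filter.

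In med7N_del, MED7 fell from 129 to 16.9 (log2 change −2.86 ± 0.11). ZPS1, of the zinc response, fell (−2.89 ± 0.11) and ALD6 fell 6.43-fold (−2.72 ± 0.12), while FLR1 (0.72 ± 0.12) and the histidine synthesis gene HIS4 (0.63 ± 0.12) rose. Methionine and sulfur genes fell in 8 of 19 cases with 4 rises (7 and 4 adjusted over the list alone), and their median of −0.07, above that of all genes, flips to 1.02 with TMM scaling (camera adjusted p = 8.69e-42). Limma called 13 of 4385 genes higher and 4343 lower, and with TMM scaling 848 and 696. In Med7_EWE3 (2 libraries), MED7 rose from 129 to 440 (1.77 ± 0.14), PHO84 fell 46.6-fold, from 519 ± 18.9 to 11.1 ± 6.24 (−5.52 ± 0.21), and the phosphate storage gene VTC3 fell (−4.03 ± 0.14), while TIP1 (1.89 ± 0.13) and the thiamine transporter gene THI7 (1.84) rose. Phosphate regulon genes fell in 11 of 11 (11 adjusted over the list alone, median −2.95, and −1.90 with TMM scaling, camera adjusted p = 2.08e-08, and adjusted p = 0.769 with an estimated correlation). Limma called 27 of 4485 genes higher and 4352 lower, and with TMM scaling 892 and 1185. In Med21_EWE4 (2 libraries against 2), SRB7, the gene of Med21, had 0.19 ± 0.21 (limma adjusted p = 0.372). It had 1.30 and was called with TMM scaling, and had 0.44 without Med21_EWE4 A, which leaves 1 library in that group. PHO84 fell 37-fold (−5.20 ± 0.19), and the serine deaminase gene CHA1 had 1 ± 0.0495 against 74.6 ± 65.8, while PUT4 (2.19 ± 0.21) and THI7 (1.71) rose. Phosphate regulon genes fell in 12 of 12 (12 adjusted over the list alone, median −3.13, and −1.91 with TMM scaling, camera adjusted p = 7e-57, and adjusted p = 0.341 with an estimated correlation). Limma called 18 of 4439 genes higher and 4364 lower, and with TMM scaling 222 and 383. In Med6_delH1, MED6 fell from 135 to 62 (−1.10 ± 0.16, and 0.07 with TMM scaling), ECM4, a glutathione transferase gene, fell 10.8-fold (−3.38 ± 0.14) and CWP1 11.8-fold (−3.34 ± 0.14). Hexose transporter genes fell in 7 of 7 (7 adjusted over the list alone, median −2.16, and −0.99 with TMM scaling, camera adjusted p = 4.41e-18, and adjusted p = 0.11 with an estimated correlation). Limma called 1 of 4554 genes higher and 4543 lower, and with TMM scaling 558 and 408.

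In the stress experiment, HS in DMSO-treated cells raised the chaperone gene SSA4 (V, 364589 to 366517) 20.4-fold, from 40.6 ± 2.13 to 829 ± 361 CPM (log2 change 4.34 ± 0.24, edgeR adjusted p = 3.25e-11). HSP26 (YBR072W, II, 382030 to 382674), a small heat shock protein gene, rose from 2.17 ± 0.616 to 171 ± 71.8 CPM (6.29 ± 0.45), and the stress genes PHM7 (4.56) and DDR2 also rose. HSP12, near the detection floor in no_stress, had 517 ± 184 CPM under HS and 0.203 ± 0.226 in no_stress. ZRT1 fell 15.3-fold, from 473 ± 45.5 to 31 ± 4.14 CPM (−3.92 ± 0.12, adjusted p = 5.7e-14), with INA1 (−3.25), INO1 (−3.24), MF(ALPHA)2 (−3.11) and YGR035C (−2.93). Stress genes of the Msn2/4 list rose in 30 of 30 cases (30 adjusted over the list alone, median 2.66, camera adjusted p = 4.64e-13, and adjusted p = 0.36 with an estimated correlation) and Hsf1 targets in 22 of 25 (22 adjusted over the list alone, median 1.33, camera adjusted p = 6.2e-08, and adjusted p = 0.4 with an estimated correlation). Proteasome genes rose in 32 of 33 (32 adjusted over the list alone, median 1.03, camera adjusted p = 1.15e-14, and adjusted p = 0.23 with an estimated correlation) and respiration genes in 29 of 33 (29 adjusted over the list alone, median 0.60, camera adjusted p = 4.85e-08, and adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis genes fell in 75 of 81 with 1 rise (75 and 1 adjusted over the list alone, median −0.68, camera adjusted p = 1.08e-12, and adjusted p = 0.4 with an estimated correlation), and pheromone response and alpha-specific genes fell in 17 of 19 with 1 rise (17 and 1 adjusted over the list alone, median −0.88, camera adjusted p = 6.47e-06, and adjusted p = 0.36 with an estimated correlation). Mediator subunit genes fell in 16 of 25 with 2 rises (16 and 2 adjusted over the list alone, median −0.25, camera adjusted p = 0.0156, and adjusted p = 0.23 with an estimated correlation). The 9 tested seripauperin genes had 2 rises and 2 falls (2 and 2 adjusted over the list alone, camera adjusted p = 0.873). Of 5547 genes, edgeR called 2046 higher and 2087 lower.

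**Figure D4:**
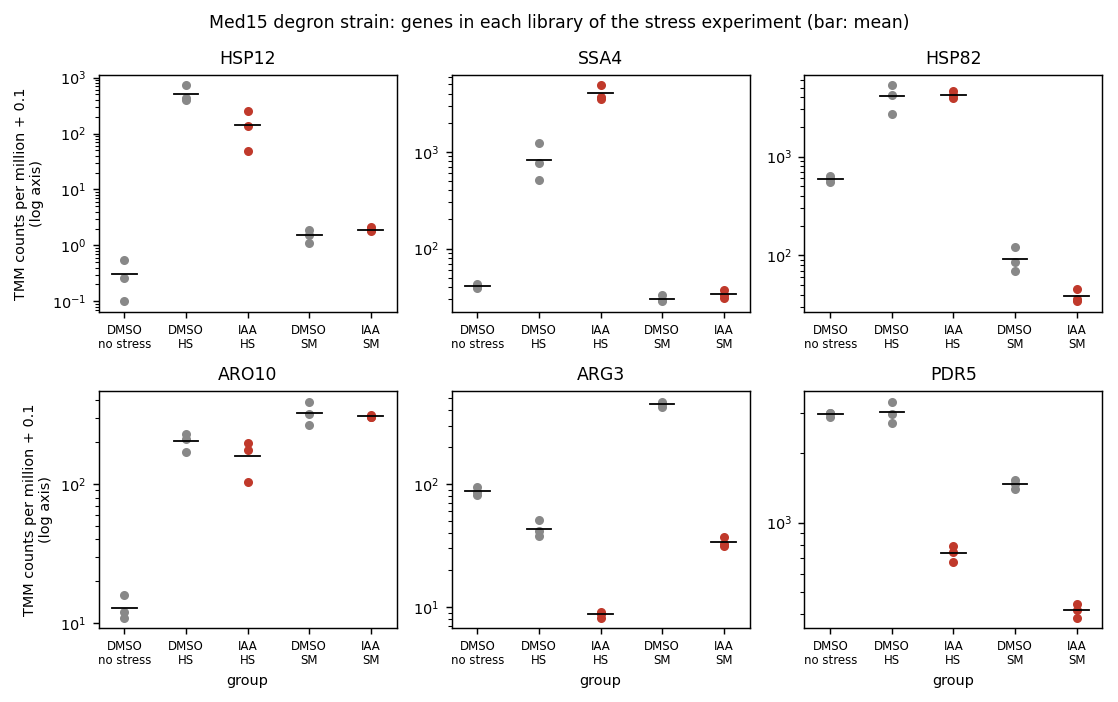
Level of HSP12, SSA4, HSP82, ARO10, ARG3 and PDR5 in each of the 15 libraries of the stress experiment, in TMM-scaled CPM plus 0.1 on a log axis, with 1 point per library and a bar at the group mean (3IAA is marked IAA). SSA4 has 40.6 ± 2.13 CPM in no_stress, 829 ± 361 under HS with DMSO and 4015 ± 740 under HS with 3IAA (mean ± SD).

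SM in DMSO-treated cells raised ARO10, of aromatic amino acid breakdown (IV, 1234218 to 1236125), 25.3-fold, from 12.9 ± 2.56 to 325 ± 62.6 CPM (log2 change 4.64 ± 0.23, edgeR adjusted p = 1.82e-11). ARO9, of the same pathway (3.39), the sulfite pump gene SSU1 (2.69) and ARG3, of arginine synthesis (2.36 ± 0.08, from 87.6 ± 6.62 to 450 ± 21.4 CPM), followed. BTN2 fell 13.9-fold, from 284 ± 25 to 20.4 ± 2.8 CPM (−3.81 ± 0.32, adjusted p = 1.47e-08), with HSP42 (−3.61), HSP82 (−2.71), SSA1 (−2.63) and ROQ1 (−2.61). Amino acid biosynthesis genes, targets of the activator Gcn4, rose in 42 of 46 cases with 3 falls (42 and 3 adjusted over the list alone, median 1.10, camera adjusted p = 2.87e-28). Hsf1 targets fell in 23 of 25 (23 adjusted over the list alone, median −1.16, camera adjusted p = 1.89e-12, and adjusted p = 0.246 with an estimated correlation). Ribosome biogenesis genes rose in 74 of 81 (74 adjusted over the list alone, median 0.46, camera adjusted p = 6.76e-15, and adjusted p = 0.387 with an estimated correlation) and cytoplasmic ribosomal protein genes in 127 of 138 with 1 fall (130 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 4.49e-24, and adjusted p = 0.246 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 46 of 67 (48 adjusted over the list alone, median −0.24, camera adjusted p = 1.71e-08, and adjusted p = 0.246 with an estimated correlation). Of 5547 genes, edgeR called 1464 higher and 1454 lower.

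Depletion of Med15 under HS left GAL11 at 708 ± 8.66 against 698 ± 44.8 CPM (log2 change 0.02 ± 0.06, edgeR adjusted p = 0.826). SSA4 rose a further 4.84-fold, from 829 ± 361 to 4015 ± 740 CPM (2.28 ± 0.20, adjusted p = 5.13e-08), and SSA3 (2.33 ± 0.14), INA1 (1.70), DPB2 (1.53) and FAT3 (1.46) also rose. DSE2 fell 4.78-fold, from 295 ± 22.6 to 61.7 ± 8.44 CPM (−2.25 ± 0.09, adjusted p = 5.31e-13), and PDR5 4.07-fold, from 3011 ± 329 to 739 ± 58.5 CPM (−2.03 ± 0.08). ADE17, of purine synthesis (−2.23), YER053C-A (−2.15) and OSI1 (−2.12) were the other falls. Cytoplasmic ribosomal protein genes fell in 131 of 138 cases with 1 rise (132 and 1 adjusted over the list alone, median −0.54, camera adjusted p = 3.8e-41, and adjusted p = 0.146 with an estimated correlation). Glycolysis genes fell in 15 of 16 (16 adjusted over the list alone, median −1.25, camera adjusted p = 4.49e-18) and drug efflux genes in 15 of 19 (15 adjusted over the list alone, median −1.10, camera adjusted p = 1.11e-12). Msn2/4 stress genes fell in 21 of 30 with 1 rise (23 and 1 adjusted over the list alone, median −0.90, camera adjusted p = 5.34e-08, and adjusted p = 0.346 with an estimated correlation), and Hsf1 targets rose in 11 of 25 with 1 fall (11 and 2 adjusted over the list alone, median 0.14, camera adjusted p = 0.00252, and adjusted p = 0.608 with an estimated correlation). Of 5547 genes, edgeR called 877 higher and 1060 lower.

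Depletion of Med15 under SM left GAL11 at 910 ± 24.7 against 881 ± 18.5 CPM (log2 change 0.05 ± 0.05, edgeR adjusted p = 0.511). ARG3 (YJL088W, X, 268799 to 269815) fell 13.4-fold, from 450 ± 21.4 to 33.4 ± 2.95 CPM (−3.75 ± 0.09, adjusted p = 8.04e-16), with INO1 (−2.76), GRE2 (−2.68), the peroxiredoxin gene AHP1 (−2.47) and FLR1 (−2.28). SRL4 rose 16.9-fold, from 3.69 ± 0.737 to 62.4 ± 5.39 CPM (4.05 ± 0.22), with CRC1 and CAT2, of carnitine transport and transfer (3.49 and 2.17), ATO2 (3.17) and CIT3, a mitochondrial citrate synthase gene (2.95). Amino acid biosynthesis genes fell in 26 of 46 cases with 7 rises (26 and 7 adjusted over the list alone, median −0.26, camera adjusted p = 0.000669, and adjusted p = 0.427 with an estimated correlation). Genes of glycolysis fell in 16 of 16 (16 adjusted over the list alone, median −1.52, camera adjusted p = 7.02e-16, and adjusted p = 0.0676 with an estimated correlation), and core histone genes in 8 of 8 (8 adjusted over the list alone, median −0.73, camera adjusted p = 2.68e-06, and adjusted p = 0.169 with an estimated correlation). The a-specific genes, markers of another mating type, rose in 7 of 8 (7 adjusted over the list alone, median 1.17, camera adjusted p = 0.000669, and adjusted p = 0.157 with an estimated correlation). Of 5547 genes, edgeR called 1166 higher and 1504 lower. The effect of Med15 depletion differed between HS and SM in 1580 genes, 805 with a more positive change under HS and 775 under SM (edgeR). The difference, HS minus SM, was −3.47 ± 0.21 in CRC1, −2.72 ± 0.16 in CIT3, 2.02 ± 0.16 in ZRT1 and 2.13 ± 0.33 in SSA4. Hsf1 targets had a more positive change under HS in 17 of 25 and Msn2/4 stress genes a more positive change under SM in 16 of 30.

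The separate tail-interacting part of Med14 and the Med14C construct differed in the changes of 4568 of 4584 genes, 4567 of them more positive in TID, and with TMM scaling in 1412, 709 of them more positive. TID minus Med14C was 4.52 ± 0.40 in BTN2, 3.72 ± 0.23 in ECM4 and 3.54 ± 0.26 in HSP82 (limma adjusted p = 1.79e-09, 4.27e-11 and 1.72e-10), and −0.63 ± 0.17 in HRP1. Med14 and Med15 depletion differed in 3847 of 3867 genes, 3844 of them more negative in Med14, and with TMM scaling in 1296, 575 of them more negative. Med14 minus Med15 was −4.26 ± 0.27 in HSP82 and −3.92 ± 0.25 in STE3, and 1.75 ± 0.25 in SER3 and 1.47 ± 0.25 in NRD1 (limma). Genes that fell after Med15 depletion were compared with other comparisons of the tail. Of its 180 falls also tested in TID, 135 fell there (9.06 if independent), and 122 of 182 fell after depletion of Med2 with Med15 (6.99). After depletion of Med15 with Med16, 154 of 181 fell (34.4). In Med16, 42 of 181 fell (2.18), and in med15del 94 of 159 (8.11). Under SM and HS, 156 and 146 of 182 fell with Med15 depletion (56.7 and 39.6). Each of these overlaps of falls passed Fisher's exact test, one-sided, after adjustment over 20 tests (adjusted p = 2.33e-157 for TID and 8.67e-55 for SM). Genes are not independent replicates in this test. Of its rises, 24 of 27 were shared with depletion of Med2 with Med15 (12.6 if independent), 14 of 27 with depletion of Med15 with Med16 (1.82), 12 of 27 each with SM and HS (4.87 and 4.5), 3 of 25 with TID (0.124) and 2 of 27 with Med16 (0.199). The 16 of 19 shared with med15del, against 16.7 if independent, did not pass (Fisher's exact test, adjusted p = 0.801).

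Genes with a TATA box in the promoter fell further than others after depletion of Med14, with a median of −2.19 over 737 genes against −1.93 over 2806 (difference −0.26; permutation test, p = 1e-05, the smallest it can give, and adjusted p = 1.88e-05). The difference was −0.16 in CCL1 and in Med10, −0.12 in Med14C, −0.08 in Med15 and 0.14 under HS. It passed in 24 of 32 comparisons, 16 with a lower and 8 with a higher median for genes with a TATA box, and without the filter on low signal in 24, 11 lower and 13 higher, so the balance turned. In Med17 it did not pass (−0.03, adjusted p = 0.187), but passed with TMM scaling (−0.04, adjusted p = 0.043) and, in the other direction, without the filter (0.05, adjusted p = 0.0015, permutation tests). Without the filter the calls of CCL1, Med10 and Med14C were lost (0.01, −0.02 and −0.02) and Med14 had −0.04. With a pseudocount of 10 the difference was −0.13 in Med14, −0.05 in Med10 and −0.05 in Med14C. These tests run across genes, which are not independent replicates.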

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

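The tests of the compound and of TMM scaling for PDR12, and both tests of the scale factor below, were chosen after seeing the results. The others were written before, although PDR12 and NRD1 were picked from the data.

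The changes of 12 pairs of comparisons were tested for a difference, and each pair had genes that differed. Med15_Taf1 against Med15 had 4564, TID against Med14C 4568, Med14 against Med15 3847, med15del against Med15 2014 and Med15 under HS against Med15 under SM 1580. Med15_Med16 against Med15 had 382, in which HXK1, a hexokinase gene, had a difference of 2.07 ± 0.28 and FRE1, of iron uptake, −1.48 ± 0.25; ribosome biogenesis genes were more negative with Med16 also depleted in 66 of 81. This count was 765 with TMM scaling, 174 without Med15 3IAA B, 222 without Med15 3IAA C, 765 without Med15 DMSO A, 168 without Med15_Med16 3IAA A and 251 without Med15_Med16 DMSO B.

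Med14 against Med17 had 1010 genes, 974 of them more negative in Med14 (519 of 855 with TMM scaling), 1614 with replicate letters as a block, 1582 without Med14 3IAA A, 1615 without Med14 DMSO B and 647 without Med14 DMSO C; ZRT1 had a difference of −2.30 ± 0.20 and TIP1 1.31 ± 0.19, and ergosterol genes were more negative in Med14 in 19 of 21. Med7C against Med7N had 1419 genes, 1366 more positive in Med7C and 53 more negative, a direction that turned with TMM scaling (72 and 242, 314 in all). It had 636 with a pseudocount of 10, 416 and 2146 without Med7C 3IAA A and B, 660 without Med7C DMSO C, 710 and 590 without Med7N 3IAA B and C, and 407, 744 and 2395 without Med7N DMSO A, B and C; the glycolysis gene TDH2 had 0.98 ± 0.14 and GRE2 −0.84 ± 0.14.

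Med15 against Med16 had 89 genes, 13 of them more positive in Med15 (80 of 207 with TMM scaling), 138 with the block, 44 without the filter, 43 without Med15 3IAA A, 44 and 46 without Med16 3IAA A and B, and 44 without Med16 DMSO C; PUT4 had −3.87 ± 0.34, ALD6 −2.35 ± 0.30 and ARG80 1.63 ± 0.26. Med2_15 against Med15 had 31 genes, 23 of them more positive in Med2_15 (6 of 16 with TMM scaling), 67 with the block, 18 without the filter, 50 with a pseudocount of 10, 12 and 17 without Med15 3IAA A and B, 19 and 51 without Med15 DMSO A and C, and 14 and 141 without Med2_15 DMSO A and C; FLR1 had −1.78 ± 0.25 and the glucose transporter gene HXT2 1.52 ± 0.23.

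Med1_5 against Med5 had 303 genes, all more negative in Med1_5, with HMX1 at −1.12 ± 0.19. With TMM scaling it had 8, of which 7 were more positive, and without the filter 2. The count was 17, 1059 and 2 without Med1_5 3IAA A, B and C, 0, 84 and 2499 without Med1_5 DMSO A, B and C, 23, 3 and 1 without Med5 3IAA A, B and C, and 2, 524 and 3 without Med5 DMSO A, B and C (limma; 2403 genes had an unadjusted p under 0.05 with all libraries). CDK8 against Med12 had 18 genes, 8 of them more positive in CDK8 (47 of 58 with TMM scaling, 2 of 2 without the filter), with CWP2, of the cell wall, at 1.33 ± 0.17 and SRX1 at −1.19 ± 0.22. The count was 4 and 2 without CDK8 3IAA A and B, 34, 3 and 2 without CDK8 DMSO A, B and C, 2, 2 and 29 without Med12 3IAA A, B and C, and 40, 5 and 6 without Med12 DMSO A, B and C.

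With 3 libraries against 3 there are 10 ways to divide 6 libraries, too few for a share under 0.05. In 29 of the 30 comparisons that could be divided so, 1 of the 10 divisions, the real one, reached the count of changed genes, and the highest other count was 12 (Med1, Med7C and Med15). In Med16, 3 of 10 reached it: 3IAA A and B with DMSO A against the rest gave 309 genes where the real division gave 114, which points to a structure of these samples beyond the treatment; among divisions that part every pair of letters, the highest other count was 1. For each of the 12 differences, 1 of 10 exchanges of treated libraries, the real one, reached the count, and the highest other was 0 (limma or edgeR).

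PDR12 rose in most degron comparisons, by 13.6-fold after Med12 depletion; it was not called in Med14 (0.23, limma adjusted p = 0.4), Med15_Taf1 (−0.07, adjusted p = 0.373) and TID (0.92, adjusted p = 0.158). Reads shared with related transporter genes do not account for it: of related genes tested in at least 11 comparisons, the highest median was 0.02 above all genes (AUS1), PDR11, tested in 3, had 0.29, and PDR18 and YNR070W were under the filter. The authors' scaling does not either, since TMM scaling called PDR12 higher in 21 of 22 comparisons. The compound 3IAA, a weak acid added to every treated degron culture, and loss of the tagged factors cannot be told apart here: PDR12 was at least 1 (log2) above the median in 1 of 6 mutant comparisons (Med7_EWE3, 1.69) and 0.51 to 0.60 above it in 3 others. On the deposited scale it fell in those 3 (med7N_del −0.51, Med21_EWE4 −0.53 and Med6_delH1 −0.61) and was not called in Med7_EWE3 (0.63, limma adjusted p = 0.0549), while TMM scaling called it higher in all 4 (adjusted p = 0.00175 to 0.0364), and it was under the filter in med15del and med16del.

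NRD1 rose while the typical gene fell in most degron comparisons with a fall, by 5.84-fold in Med15_Taf1, but fell in CCL1 (−0.35, limma adjusted p = 0.013), med7N_del (−0.26), Med7_EWE3 (−0.37) and Med21_EWE4 (−1.08). Reads of a neighbouring gene do not account for it, since MRPL17 or RAD50 was at least 1 above the median in 0 of 11 comparisons. Whether RNAs held down by early termination rose with it cannot be told from 5 such genes in Med14, whose median was 0.40 above that of all genes, with URA8 at 1.62 and ADE12 at −0.91. Over the 11 comparisons, the median of those tested, minus that of all genes, ran from −0.47 (Med7_EWE3) to 1.08 (Med15_Taf1). It was −0.03 in Med10, although NRD1 rose there.

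The typical gene fell by more than 2-fold in the deposited values of 11 comparisons. In Med19 and Med21_EWE4, with whole reads in every library, fewer reads do not account for it: the lowest ratio of mean reads was 0.945 (Med21_EWE4), where the signal ratio was 0.428. For the other 9, whole reads were found in both arms in 0 comparisons, so this cannot be told. A change of the scale factor alone does not account for the calls, since TMM scaling still called at least 1863 genes in each of the 6 comparisons with the largest falls. The size of the fall may be set by the authors' scale factor: with TMM scaling the highest median of the 6 was 0.06, which follows from that scaling itself, so the explanations cannot be told apart without the basis of the scale.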

How the results depend on the processing

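Of 2409 values of 218 named-gene results under other settings, 2361 kept direction and call, 37 lost the call, 4 gained it and 7 reversed. The reversals were all with TMM scaling: CCL1 in CCL1 0.33, MED7 in Med7N 0.10, RGR1 in Med14 0.49 and in Med14C 0.30, GAL11 0.22 and TAF1 0.26 in Med15_Taf1, and MED6 in Med6_delH1 0.07; TMM removes the shift shared by all genes by construction. The DESeq2 test and DESeq2 size factors kept 5 of 5 stress counts each within 1.5 times, and edgeR on recovered whole reads 11 of 12. Leaving out 1 library kept 250 of 333 counts within 1.5 times and moved 83.

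Counts of changed genes moved by over 1.5 times with TMM scaling to 2613 in CCL1, 322 in Med1, 213 in Med1_5, 547 in Med2_15, 1082 in Med7C, 1764 in Med7N, 1863 in Med14, 2604 in Med14C, 374 in Med15, 2185 in Med15_Med16, 267 in Med16, 2057 in Med17, 1803 in Med19, 1723 in Med31, 1544 in med15del, 1544 in med7N_del, 2077 in Med7_EWE3, 605 in Med21_EWE4 and 966 in Med6_delH1. For differences TMM gave 2112 in Med15_Taf1 against Med15, 765 in Med15_Med16 against Med15, 16 in Med2_15 against Med15, 8 in Med1_5 against Med5, 58 in CDK8 against Med12, 314 in Med7C against Med7N, 1412 in TID against Med14C, 1296 in Med14 against Med15, 207 in Med15 against Med16 and 956 in med15del against Med15. With replicate letters as a block the counts were 1007 in CDK8, 484 in Med5, 3743 in Med2_15, 1084 in TID, 2420 in Med15_Med16 and 609 in Med16, and for differences 67 in Med2_15 against Med15, 2776 in Med1_5 against Med5, 170 in CDK8 against Med12, 1614 in Med14 against Med17, 3032 in Med7C against Med7N and 138 in Med15 against Med16; libraries of 1 letter were alike across treatment (each correlation above 0.1, with at least 3 pairs) in 15 of 32 comparisons. Without the filter, more genes were tested: 5361 changed in Med14, 5180 in med15del and 2501 in med16del, and 18 differed in Med2_15 against Med15, 2 in Med1_5 against Med5, 2 in CDK8 against Med12 and 44 in Med15 against Med16. A pseudocount of 0.1 with a mean of at least 2, chosen after seeing the data, gave 53 in Med5, 4716 in med15del and 2262 in med16del. EdgeR on recovered reads, run after seeing the data, gave 63 in Med5. A pseudocount of 10 gave 50 in Med2_15 against Med15 and 636 in Med7C against Med7N. Except for the construction of TMM and of the missing filter, the cause was not tested.

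Leaving out 1 library gave 468 to 3761 genes in Med1, 14 to 166 in Med5, 1795 to 3870 in Med1_5, 696 to 4397 in Med2_15, 178 to 612 in Med7, 377 to 1223 in Med12, 149 to 502 in TID, 133 to 648 in Med15, 788 to 1637 in Med15_Med16 and 62 to 152 in Med16. For differences the range was 168 to 765 in Med15_Med16 against Med15, 12 to 141 in Med2_15 against Med15, 0 to 2499 in Med1_5 against Med5, 2 to 40 in CDK8 against Med12, 647 to 1615 in Med14 against Med17, 407 to 2395 in Med7C against Med7N and 43 to 122 in Med15 against Med16 (limma); the cause was not tested.

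Of 676 list tests 367 passed, and 396 passed with TMM scaling, 353 with the block, which changed 68 calls, 366 with a pseudocount of 10 and 9 with an estimated correlation. The TATA difference reversed without the filter to 0.01 in CCL1, 0.06 in Med15_Taf1, 0.05 in Med17, 0.04 in med7N_del, 0.09 in Med7_EWE3 and 0.02 in Med21_EWE4, and with a pseudocount of 10 to 0.04 in Med15_Taf1; the cause was not tested. The wider window kept 31 of 32 TATA results. Depth is not known for 60 libraries, and its effect on calls was not tested there.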

Other observations

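The overlaps of changed genes were chosen after seeing the results.

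After Med7 depletion, ribosome biogenesis genes, which code for factors that build ribosomes, had a median of 0.17 with 1 fall among 81 (1 adjusted over the list alone, and 13 rises with 1 fall with TMM scaling), above all genes (camera adjusted p = 1.22e-15, and adjusted p = 0.422 with an estimated correlation). Of 182 genes that fell after Med15 depletion, 147 also fell after Med7 depletion, where 16.6 would do so if the calls were independent (Fisher's exact test, one-sided, adjusted p = 4.56e-130). Med16 depletion and deletion of its gene shared 37 falls (4.06 if independent) and 19 rises (6.35).

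After Med16 deletion, methionine and sulfur genes rose in 8 of 14 cases (8 adjusted over the list alone, median 0.79, camera adjusted p = 8.82e-09, and adjusted p = 0.578 with an estimated correlation) and respiration genes in 11 of 11 (11 adjusted over the list alone, median 0.53, camera adjusted p = 0.000955, and adjusted p = 0.708 with an estimated correlation). Across genes, which are not independent replicates, 81 of 376 pairs of degron and mutant comparisons without shared libraries had a Pearson correlation of their log2 changes above 0.5.

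The group Med15_Spt7_DMSO had no 3IAA partner in the files and entered no comparison. Its replicates A, B and C had totals of 648043, 691330 and 739002 and median signals of 65.61, 69.45 and 72.96.

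The Med31 libraries carry a genotype label with the degron on MED19. Scaled to the total of each library in the manner of CPM, SOH1, the gene of Med31, had 85.4, 91.9 and 84.4 in Med31 DMSO libraries and 154, 137.8 and 156.8 in Med19 DMSO libraries. ROX3, the gene of Med19, had 181, 220.2 and 212.8 in the first and 144.4, 124.5 and 130.8 in the second. In DMSO, RGR1 was 11.6 times the median of the other strains in Med14C and 8.86 times in TID, which carry plasmid copies of MED14, and MED7 was 2.47 times in Med7C and 2.61 times in Med7N.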
